A study of Danio rerio with 4 samples.

How the data were processed

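Gene expression was measured by RNA sequencing in 4 libraries of EGFP-positive cells sorted from adult zebrafish brains, each a pool of 6 brains. Per the labels' protocols, the brains were dissociated with Liberase, cells carrying a pdgfrb-driven EGFP were sorted into a lysis reagent, and the extracted RNA was amplified before standard Illumina library preparation. The submitters' processing notes name bcl2fastq without a version, R 3.2.2 and the genome build GRCz10; the aligner, the counting tool and the annotation are not given in the sources used here. The authors deposited whole-number read counts per Ensembl gene ID, with 1 column per library and no normalization in the values. They also deposited YuGene values, a score between 0 and 1 per gene and library set within each library. Amplified reads without molecular identifiers are not independent molecules, so floors and sampling noise here cover counting error only.

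All 4 samples carry titles and source names that call them pericytes, and they form the only group. The 4 columns of each table match no sample number and were used as unnumbered libraries of that group, with 0 columns of values left out. Gene symbols came from a table that pairs Ensembl IDs with names, which gave a symbol for 26269 of the 32105 IDs, and 5836 IDs stayed without. Many of its symbols are in human style without the suffix of zebrafish gene copies, and 4144 IDs share a symbol. Counts of near-identical copies, such as those of GLUL, FABP7, TAGLN, VEGFA or MFSD2A, are uncertain where the counting could split reads between them. Before the data were examined, 20 gene lists with 395 entries were fixed. Of these entries 374 were matched, 65 of them by taking every ID whose capital symbol equals the entry without its final letter, and 21 were not. Of the 24 pericyte IDs 3 are also in another list, 1 each in the notch pathway, angiogenic ligand and PDGF and TGF-beta reception lists.

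Counts were scaled with edgeR 4.0.16 (TMM factors of 1.03, 0.948, 1.04 and 0.988 for B1 to B4) in R 4.3.3. Genes with at least 1 CPM in at least 2 libraries were tested. A model with a single mean per gene was fitted with edgeR's quasi-likelihood method, and its level was tested, two-sided, against the median fitted CPM of the tested genes, with Benjamini-Hochberg adjustment at 0.05. Because edgeR's own test function takes no model with an intercept alone, the F statistic was formed as that function forms it, from the drop in deviance and the squeezed quasi-dispersion. The standard error is taken at the fitted level. On simulated counts for the 17283 tested genes with known levels, the test called 50 of 50 genes at 4 times the reference level and 50 of 50 at 0.25 times, 33 of 50 at 2 times and 25 of 50 at 0.5 times, and 2 of 200 genes at the reference level.

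Lists were compared by the difference of their medians of mean log2 CPM with a prior count of 2, pericyte minus the other list, leaving out shared genes. The p came from a two-sided permutation of genes between the lists with 100000 resamples, adjusted over 19 comparisons, and describes these libraries, since genes are not replicates. The exact sign-flip test over 4 libraries has a smallest possible p that rounds to 0.13. On random lists of 24 and 21 genes from the 17283 tested, the permutation gave p under 0.05 in 12 of 200 pairs with no shift and in 195 of 200 with a shift of 3 log2 units. Among 10000 random lists from all IDs in the table, the radial glia, pericyte, fibroblast, proliferation, notch pathway, housekeeping, PDGF and TGF-beta reception and immediate early and stress medians lay at percentile 100. The oligodendrocyte, basement membrane and angiogenic ligand lists lay at percentiles 99.9, 99.9 and 99.2, neuron at 96.05, lymphatic at 91.3, endothelium at 85.3, microglia at 80.45, smooth muscle at 73.7, epithelium at 53.9, erythrocyte at 40.3, neutrophil at 27.2 and lymphocyte at 19.2. All IDs include many without counts, so the tested members were also compared with as many random tested genes. There the radial glia, immediate early and stress, PDGF and TGF-beta reception and housekeeping lists lay at percentile 100, proliferation at 99.99, pericyte at 99.94, fibroblast at 99.69, smooth muscle at 97.74, basement membrane at 96.89, notch pathway at 96.58 and oligodendrocyte at 94.46. Angiogenic ligands lay at 59.47, neutrophil at 52.06, neuron at 36.64, lymphatic at 34.12, epithelium at 9.99, microglia at 4.55, erythrocyte at 3.48, endothelium at 1.93 and lymphocyte at 0.12.

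Variable genes were those of mean CPM of at least 10 with an edgeR tagwise biological coefficient of variation of at least 1. This estimate is drawn towards a trend with abundance, and the common value was 0.539. On simulated counts it passed 62 of 161 genes given a coefficient of variation of 2 and 0 of the genes given 0.3, out of 16978 genes in that step. All other genes of the simulation were given 0.3, below the common value of the data, so these rates need not hold for the data. The share of variable genes in each list was tested with a two-sided Fisher's exact test. Pairs of libraries were compared by correlation and, to look for a library deposited more than once, by a chi-square over genes with at least 10 counts in the pair. The genes named in the text were chosen by a rule fixed before the data were examined, which took 19 focus genes, the 4 most abundant members of each list, the 20 most abundant genes with a symbol and the 10 most variable with a symbol, 111 IDs in all. ENSDARG00000080337, LUM, OSR2 and the genes of the closing observations were named after their values were seen. Alternatives were DESeq2 1.42.0 size factors and its Wald test, limma 3.58.1 with voom, total counts, other filters, prior counts and thresholds, list means, YuGene values and leaving out each library. The number of list members on each side of the reference level without each library was added after the data had been seen, because B1 stood apart. Permutations and random lists were drawn with numpy 2.4.6 in Python 3.11.15. No genome annotation was used here, so no correction for gene length or base composition was made.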

Results

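RNA sequencing was carried out on 4 libraries of a single kind of sample, cells sorted by fluorescence for EGFP driven by pdgfrb regulatory sequence from enzymatically dissociated brains of adult zebrafish. The receptor encoded by pdgfrb is a marker of pericytes, the mural cells that lie on capillaries, and of related perivascular cells. Each library was made from a pool of 6 brains, and the RNA was amplified before sequencing. The design text speaks of 3 preparations whereas 4 samples are listed, and all 4 were used. A cell type tag on the samples reads muLEC, while their titles and source names say pericyte, which was followed here. The columns of the count table match no sample number, so the libraries are called B1 to B4 after those columns. Total counts were 33270774 in B1, 38945855 in B2, 34403918 in B3 and 40441253 in B4. At these depths 3 counts correspond to between 0.0751 and 0.0879 CPM (the read count scaled to a common library size), a floor that covers counting error only. The labels name 6 brains per sample and no other separation of the pools. The p-values of single genes therefore measure the spread between these 4 pools, which may be partly technical. Those of list comparisons by permutation, and of Fisher's exact test, compare genes and do not measure that spread.

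With a single group, the questions the design allows are which genes are abundant in the sorted cells, which cell types' marker genes are found beside those of pericytes, and how far the 4 pools differ. Of 32105 Ensembl gene IDs, 15056 reached 1 CPM in all 4 libraries, and between 16753 and 16910 did so in a single library. The level of each of 17283 genes was tested against the median tested gene, called the reference level, at 12.6 CPM. By edgeR's quasi-likelihood test 6362 genes (36.8%) lay above it and 5746 (33.2%) below it, at a Benjamini-Hochberg adjusted p under 0.05. Levels of different genes are compared as counts without correction for transcript length.

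The most abundant genes with a symbol were malat1, a nuclear long non-coding RNA, at 44602 ± 20684 CPM (mean ± SD, n = 4 here and below), and epd, which encodes the secreted glycoprotein ependymin, at 33905 ± 26311 CPM. The glutamine synthetase gene GLUL (ENSDARG00000099776) at 16803 ± 7006 CPM and the glutamate transporter gene SLC1A2 at 9337 ± 2322 CPM were among the 20 most abundant. FOS at 11499 ± 3697 CPM and JUN at 10803 ± 13383 CPM, both immediate early transcription factors, and the anti-proliferative gene BTG2 at 7429 ± 10864 CPM were among them too. Others of the 20 were the heat shock gene hsp70l at 4672 ± 1376 CPM, selenop at 4472 ± 1311 CPM, CKB at 3875 ± 1483 CPM, GGCT at 5577 ± 4489 CPM and the mitochondrially encoded MT-CO1 at 4303 ± 2042 CPM. The uncharacterised loci si:ch211-276i12.12, at 14801 ± 7370 CPM, and si:ch211-251b21.1, at 7317 ± 4856 CPM, were among the 20 as well. JUN and BTG2 were carried by B1, at 30863 and 23719 CPM against at most 4586 and 2245 CPM in the other 3 libraries. Without B1 their means were 4116 and 1999 CPM, and without B4 the mean of GGCT was 3619 CPM. The single most abundant ID, ENSDARG00000080337, has no symbol and stood at 45016 ± 21634 CPM.

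The pericyte markers were mostly abundant. PDGFRB, the gene whose regulatory sequence drove the sort, reached 115 ± 75.5 CPM, 3.19 ± 0.37 (SE) log2 units above the reference level (edgeR adjusted p = 4.82e-05). NOTCH3, a receptor of mural cells, reached 170 ± 123 CPM, and the G protein signalling regulators rgs5b and RGS5 reached 272 ± 283 and 49.2 ± 25.5 CPM. KCNE4, a potassium channel subunit gene, stood at 319 ± 424 CPM and the transcription factor gene ZIC1 at 263 ± 142 CPM. Of the 21 tested IDs of the pericyte list, 15 lay above the reference level, 3 below it and 3 on neither side, and the counts adjusted over the list alone were the same. The channel genes ABCC9, at 16.0 ± 4.92 CPM, and KCNJ8, at 11.3 ± 2.09 CPM, were among the 3 that did not pass. Without B1 the level of ABCC9 passed at log2 0.49, and its edgeR adjusted p ran from 0.0372 to 0.852 over the alternatives. The proteoglycan gene CSPG4 lay below the reference level at 1.19 ± 0.823 CPM. KCNE4 was 955 CPM in B1 against at most 116 CPM in the others, and rgs5b was 26.8 CPM in B1 against 178 to 679.6 CPM. Without B1 the means of KCNE4 and NOTCH3 were 107 and 109 CPM, and without B2 the mean of rgs5b was 136 CPM.

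Single marker genes of other vascular cells were compared with PDGFRB within each library. PDGFRB was higher in 4 of 4 libraries than kdrl, the endothelial VEGF receptor gene (5.48-fold, log2 difference 2.45 ± 0.56, SD), and cdh5, the endothelial cadherin gene (29.6-fold, 4.89 ± 1.31). The same held for the lymphatic genes PROX1 (13.4-fold, 3.75 ± 0.92) and lyve1b (10.9-fold, 3.44 ± 1.42, and 6.71-fold without B1). It was also higher in 4 of 4 libraries than the lymphatic receptor gene FLT4 (3.06-fold, 1.61 ± 0.91). Against the smooth muscle gene TAGLN (ENSDARG00000033466) the difference was 0.04 ± 1.72 and against the mannose receptor gene MRC1 it was 0.33 ± 0.62, both smaller than their spread. The difference from TAGLN was -0.76 without B1. Over the 18 genes compared, the exact sign-flip test on 4 libraries gave at best its smallest possible p, which rounds to 0.13, and its Benjamini-Hochberg adjusted values began at 0.205.

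**Figure D1:**
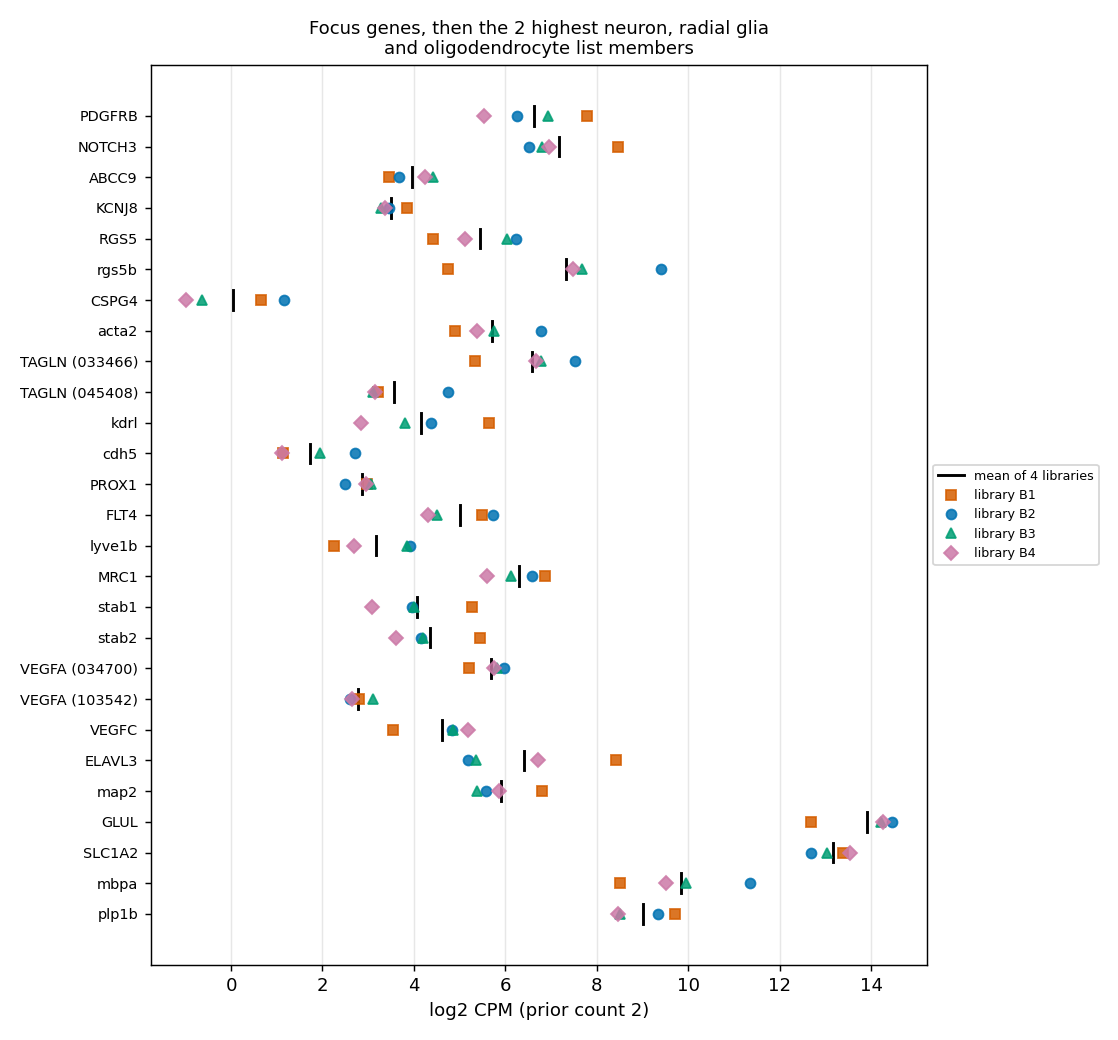
Level of the focus genes and of the 2 most abundant members of the neuron, radial glia and oligodendrocyte lists, as log2 CPM with a prior count of 2 on the horizontal axis. Each symbol is a library, the black bar is the mean of the 4, and digits in brackets are the end of the Ensembl ID where copies share a symbol; GLUL and SLC1A2 lie far to the right of PDGFRB, and B1 is the highest library in ELAVL3 and the lowest in rgs5b.

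Genes of the other mural and perivascular cell types were compared as lists. The median pericyte list gene stood at 37.0 ± 11.9 CPM and the smooth muscle list median at 3.89 ± 2.43 CPM. List differences here and below are between medians of mean log2 CPM, so they differ from the ratio of such CPM values. By that measure the pericyte list lay 3.61 log2 units above smooth muscle, and was higher in 4 of 4 libraries. The adjusted p was 0.0241 by permutation of genes over the 19 lists compared. Among smooth muscle genes 8 of 15 tested lay above the reference level and 4 below, led by tpm1 at 125 ± 51.1 CPM, TAGLN (ENSDARG00000033466) at 109 ± 58.2 CPM, ITGA8 at 74.0 ± 53.4 CPM and the contractile actin gene acta2 at 58.9 ± 35.7 CPM. The second copy of TAGLN (ENSDARG00000045408) stood at 13.3 ± 8.90 CPM and did not pass. Fibroblast genes were close to the pericyte list, with a median of 30.1 ± 12.1 CPM and a difference of 0.43 log2 units (permutation adjusted p = 0.62). Of 20 tested fibroblast IDs 14 lay above and 2 below the reference level, among them DCN at 746 ± 358 CPM and the fibrillar collagen genes COL1A2 at 577 ± 669, col1a1a at 508 ± 586 and COL1A1 at 471 ± 526 CPM. By DESeq2 14 fibroblast IDs lay above and 3 below, and by limma-voom 12 and 4. The collagen means rest on B3, where COL1A2 was 1572 CPM against 136 to 356 CPM in the others. Without B3 the means of COL1A2, col1a1a and COL1A1 were 246, 219 and 218 CPM. The mean of ITGA8 was 47.3 CPM without B4, and that of the second TAGLN copy was 8.88 CPM without B2. The difference from smooth muscle was 0.56 with tested members alone and 1.92 with list means, and did not pass in either (permutation adjusted p of 0.0145 to 0.262 over the alternatives). Without B1 the smooth muscle IDs below the reference level were 2.

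Endothelial genes were mostly low. The endothelium list had a median of 4.85 ± 0.988 CPM, 3.14 log2 units under the pericyte list (permutation adjusted p = 0.0131, lower in 4 of 4 libraries), and 14 of its 22 tested IDs lay below the reference level against 4 above. The 4 above were the lipid transporter gene MFSD2A in both copies, at 108 ± 22.0 CPM for ENSDARG00000035909 and 65.7 ± 22.9 CPM for ENSDARG00000030630, the glucose transporter gene SLC2A1 at 43.6 ± 13.4 CPM and the tight junction gene CLDN5 at 71.4 ± 112 CPM. CLDN5 was 240 CPM in B1 and at most 20.3 CPM in the others, and its level did not pass without B1 (log2 0.29 against 2.50) or by limma-voom (1.24). Its adjusted p by edgeR, DESeq2 or limma-voom ran from 0.000469 to 0.207 over the alternatives. kdrl stood at 22.9 ± 18.8 CPM (13.9 CPM without B1) without passing, and cdh5 lay below the reference level at 3.63 ± 2.05 CPM. With list means the difference from the pericyte list was 1.95 and did not pass (permutation adjusted p of 0.00247 to 0.0625 over the alternatives).

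The list of lymphatic and muLEC genes, the cell type that the tag on the samples names, had a median of 19.0 ± 13.1 CPM and was 2.06 log2 units under the pericyte list, a difference that did not pass (permutation adjusted p = 0.122, lower in 3 of 4 libraries). In B1 the list lay above the pericyte list (-0.68), and without B1 its median was 12.6 CPM. The mean of the per-library differences was smaller than 2.06, at 1.12 ± 1.28 log2 units. Of its 11 IDs 4 lay above and 3 below the reference level. Those above were the nuclear receptor gene NR2F2 at 86.8 ± 12.4 CPM, MRC1 at 82.3 ± 29.5 CPM, FLT4 at 35.0 ± 16.4 CPM and the scavenger receptor gene stab2 at 22.9 ± 14.0 CPM. PROX1, the lymphatic transcription factor gene, lay below at 7.34 ± 1.22 CPM, and stab1 at 19.5 ± 12.9 CPM and lyve1b at 10.1 ± 5.36 CPM did not pass. The call of stab2 (log2 0.86, edgeR adjusted p = 0.0382) was lost without B1, B2 or B3 (0.35, 0.89 and 0.87) and by limma-voom (0.69), with adjusted p of 0.0303 to 0.0931 over the alternatives. That of PROX1 (log2 -0.78, edgeR adjusted p = 0.0271) was lost without B2, B3 or B4 (-0.75, -0.93 and -0.90), with adjusted p of 0.00417 to 0.0843. The number of IDs below the reference level was 1 without B2 and 1 without B4, and with only tested members the list difference was 2.26 and passed (permutation adjusted p of 0.0349 to 0.765 over the alternatives).

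Radial glia genes were the most abundant of the cell type lists. Their median was 252 ± 34.7 CPM, and they took 4.96 ± 0.921% of all counts. By medians of mean log2 CPM their level was 6.36-fold that of the pericyte list (log2 difference -2.67, permutation adjusted p = 0.0242). The direction was the same in 4 of 4 libraries. Of 20 tested IDs 15 lay above and 3 below the reference level, led by GLUL (ENSDARG00000099776), SLC1A2, the gap junction gene GJA1 at 6746 ± 1725 CPM and the fatty acid binding protein gene FABP7 (ENSDARG00000007697) at 6947 ± 4078 CPM. FABP7 was 57.0-fold and GLUL 155-fold above PDGFRB, in 4 of 4 libraries each, and 114-fold and 268-fold without B1. Oligodendrocyte genes had a median of 36.0 ± 16.4 CPM, 0.63 log2 units under the pericyte list (permutation adjusted p = 0.548). In B1 they lay above it (-1.30), and the mean of the per-library differences was 0.10 ± 1.03. By the edgeR test 9 of 14 IDs lay above and 3 below the reference level. The myelin genes mbpa at 1170.2 ± 984 CPM and plp1b at 551 ± 237 CPM led that list, and cnp stood at 171 ± 199 CPM. The mean of mbpa was 695 CPM without B2, and that of cnp was 71.8 CPM without B1. Without B2 the edgeR test placed 0 of 12 oligodendrocyte IDs below the reference level, and 1 at an unadjusted p under 0.05.

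Neuronal genes were lower, with a median of 7.40 ± 5.63 CPM, 2.44 log2 units under the pericyte list (permutation adjusted p = 0.0241, lower in 4 of 4 libraries). Of 21 tested IDs 6 lay above (5 when adjusted over the list alone) and 4 below the reference level. The RNA-binding protein genes ELAVL3 at 131 ± 145 CPM and ELAVL4 at 37.7 ± 19.6 CPM, map2 at 64.9 ± 32.2 CPM and SNAP25 at 31.3 ± 14.3 CPM led the list. B1 held more of these transcripts than the other libraries, since 25 of the 27 neuron IDs were higher there than in the mean of B2 to B4, by a median of 1.46 log2 units. The same share over all genes is not given here. By median log2 CPM, B1 was also highest for the lymphatic (5.26 against at most 3.92) and oligodendrocyte lists (5.88 against at most 5.01). It was highest too for the notch pathway, microglia and angiogenic ligand lists, and for none of the remaining lists. A rise in B1 was thus not particular to neuron genes. Without B1 the neuron list median was 4.73 CPM, the mean of ELAVL3 was 60.3 CPM and the list lay 3.29 log2 units under the pericyte list. Without B1 the neuron IDs below the reference level were 9, and without B2, B3 or B4 they were 2, 2 and 1. At an unadjusted p under 0.05 by edgeR the last 3 counts were 4, 4 and 2. The list difference was 1.80 with list means and did not pass (permutation adjusted p of 0.00285 to 0.0731 over the alternatives).

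**Figure D2:**
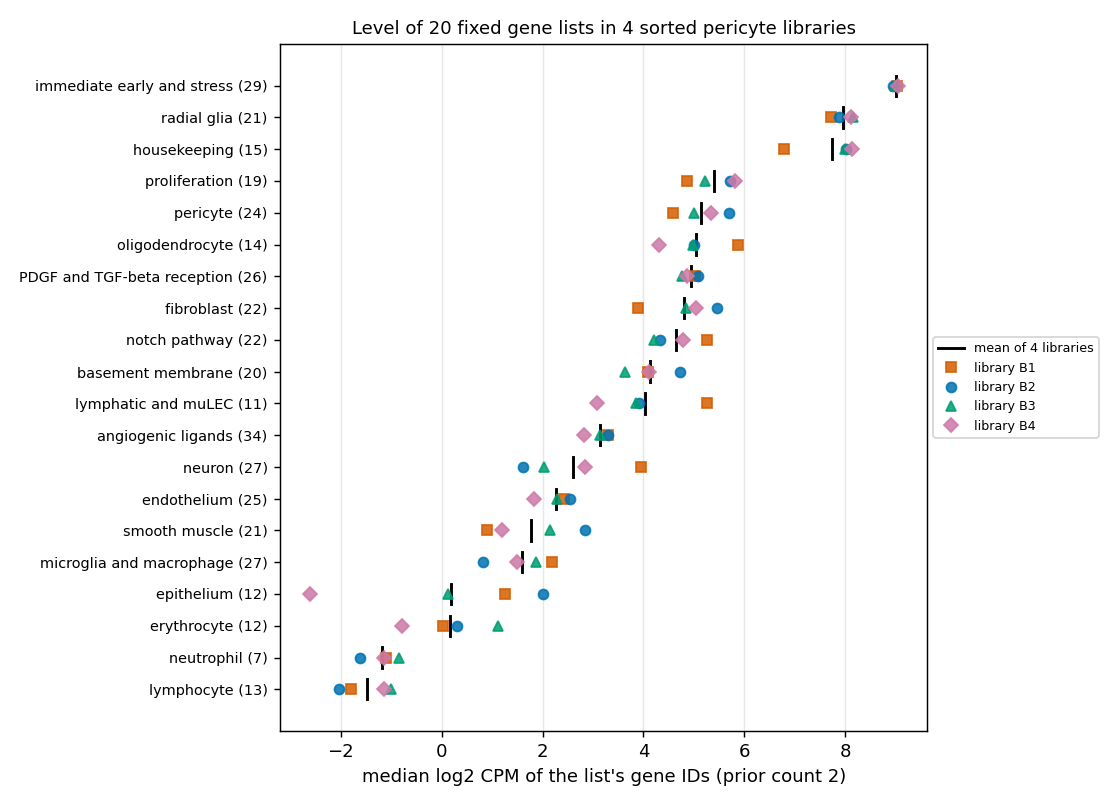
Median log2 CPM (prior count 2) of the gene IDs of each of 20 fixed lists, with the number of IDs in brackets, in the 4 libraries. Symbols are libraries and black bars their mean; by the mean of the 4 libraries, immediate early and stress genes and radial glia genes lie highest and lymphocyte genes lowest, and the housekeeping list is lower in B1 (6.78) than in the other 3 libraries (8.0 to 8.13).

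Blood, immune and epithelial genes were low as lists, with single abundant members. Some entries of these lists found no ID and are not covered. They were 2 of 13 erythrocyte entries (the globin genes hbba1 and hbba2), 3 of 10 neutrophil entries (mpx among them), 2 of 15 lymphocyte entries and 3 of 23 microglia entries. The lymphocyte list was 6.97 log2 units under the pericyte list (permutation adjusted p = 0.00456), with 5 of 5 tested IDs below the reference level and 0 above it by edgeR (also at an unadjusted p under 0.05), DESeq2 or limma-voom. Among those below were il7r at 3.45 ± 1.85, PAX5 at 1.85 ± 0.540, ZAP70 at 1.73 ± 1.21 and lck at 1.12 ± 0.517 CPM. The erythrocyte list was 5.40 log2 units under it (0.0129) and the epithelium list 4.61 under it (0.0241), both lower in 4 of 4 libraries. The lymphocyte difference was 6.07 without B2, and the epithelium difference was 5.27 without B2 and 3.83 without B4. Of 6 tested erythrocyte IDs 2 lay above the reference level, the carbonic anhydrase gene cahz at 409 ± 168 CPM and blvrb at 26.8 ± 12 CPM, and 2 below, among them hemgn at 2.86 ± 1.06 CPM. The call of blvrb (log2 1.09, edgeR adjusted p = 0.0142) was lost without B2, B3 or B4 (0.87, 0.83 and 0.97) and by limma-voom (0.92), with adjusted p of 5.89e-05 to 0.0995 over the alternatives. In each of those 3 cases 1 erythrocyte ID lay above. The globin gene hbaa1 stood at 5.17 ± 5.35 CPM (2.61 CPM without B3) and did not pass in the edgeR test of all 4 libraries (log2 -1.29). It passed as low without B3 (-2.36), by DESeq2 (-1.29) and by limma-voom (-1.91), with adjusted p of 0.0181 to 0.217 over the alternatives. In the epithelium list krt8 at 274 ± 73.7 CPM was the 1 ID above, and 2 of 8 lay below (1 when adjusted over the list alone, and 1 without B2 or without B3). The keratin genes krt4 at 15.8 ± 7.60, krt91 at 16.2 ± 14.1 and krt5 at 14.8 ± 13.2 CPM did not pass. Without B1 the means of krt91 and krt5 were 9.25 and 8.36 CPM.

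Microglia and macrophage genes were 3.47 log2 units under the pericyte list (permutation adjusted p = 0.0129, lower in 4 of 4 libraries), with 11 of 18 tested IDs below the reference level and 4 above. Those above were the apolipoprotein genes apoeb at 1434 ± 803 and apoc1 at 56.4 ± 37.2 CPM and the invariant chain genes cd74b at 250.3 ± 185 and cd74a at 202 ± 122 CPM. The neutrophil list was 6.85 log2 units under the pericyte list (0.034 by permutation), with 1 of 3 tested IDs above, the myc family gene mych at 702 ± 399 CPM, and 1 below, NCF1 at 6.82 ± 1.65 CPM. MMP9 at 13.2 ± 6.16 CPM did not pass, and npsn at 0.298 ± 0.140 CPM was under the filter. NCF1 (log2 -0.89) lost its call by edgeR without B3 (-1.01) or without B4 (-1.03), with adjusted p of 0.00315 to 0.0652 over the alternatives. This left 0 neutrophil IDs below, and 1 at an unadjusted p under 0.05. The neutrophil difference was 1.86 with tested members alone and 3.21 with list means, and passed in neither (permutation adjusted p of 0.0279 to 0.262 over the alternatives).

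Immediate early and stress genes were the highest of the 20 lists. Their median was 513 ± 15.2 CPM. By medians of mean log2 CPM their level was 12.5-fold that of the pericyte list (log2 difference -3.65, permutation adjusted p = 0.00456). The direction was the same in 4 of 4 libraries. Of 28 tested IDs 25 lay above the reference level (26 adjusted over the list alone). By edgeR (also at an unadjusted p under 0.05), DESeq2 or limma-voom 0 lay below it. FOS, JUN, JUNB (ENSDARG00000104773) at 5234 ± 3218 CPM and hsp70l led them, and together the list took 5.38 ± 2.91% of all counts. Housekeeping genes were 5.72-fold above the pericyte list (log2 difference -2.52, permutation adjusted p = 0.0333), with 11 of 15 above and 1 below the reference level, led by the actin genes actb2 at 4072 ± 686 and actb1 at 2898 ± 589.6 CPM, GAPDHS at 3811 ± 1223 CPM and eef1a1l1 at 1511 ± 265 CPM. That difference did not pass without B4 (-2.35) or on the deposited YuGene scale (-0.284), with permutation adjusted p of 0.01 to 0.0727 over the alternatives. Of 17 tested proliferation IDs 12 lay above and 1 below the reference level (2 below when adjusted over the list alone), led by the replication genes PCNA at 158 ± 42.4, MCM7 at 212 ± 240, MCM2 at 110.3 ± 32.1 and MCM3 at 100.1 ± 49.8 CPM. MCM7 was 571 CPM in B1 and at most 123 CPM in the others. Without B1 the means of MCM7 and JUN were 92.2 and 4116 CPM. The proliferation list did not differ from the pericyte list by the test (0.13, permutation adjusted p = 0.975), and its sign depends on the summary, since the per-library differences had a mean of -0.26 and were negative in 4 of 4 libraries.

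Genes of the vessel wall and of signalling between vascular cells were grouped in 4 lists. Of 28 tested angiogenic ligand and receptor IDs 12 lay above and 7 below the reference level, among them ANGPTL4 at 503 ± 66.4 CPM, the chemokine gene CXCL12 at 413 ± 184 CPM, igf2b at 92.3 ± 25.5 CPM and VEGFA (ENSDARG00000034700) at 52.4 ± 11.1 CPM. VEGFC, the lymphatic growth factor gene, lay above at 26.3 ± 10.5 CPM (edgeR adjusted p = 0.00996) and the second VEGFA copy (ENSDARG00000103542) below at 6.91 ± 1.16 CPM (0.0187). The call of VEGFC (log2 1.06) was lost by edgeR without B2, B3 or B4 (0.94, 0.92 and 0.77), with adjusted p of 9.31e-05 to 0.0937 over the alternatives. That of the second VEGFA copy (log2 -0.87) was lost by edgeR without B2 or B4 (-0.89 and -0.91), with adjusted p of 0.00126 to 0.0691. The list was 2.03 log2 units under the pericyte list (permutation adjusted p = 0.0464), a call that was lost without B1 (2.11), B2 (1.79), B3 (1.95) or B4 (1.96). It was also lost with tested members alone (1.80), with list means (1.14) and on the YuGene scale (0.335), with permutation adjusted p of 0.0464 to 0.327 over the alternatives. Without B4 the IDs below numbered 3 by edgeR, and 7 at an unadjusted p under 0.05.

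Basement membrane genes had 10 of 19 tested IDs above and 2 below the reference level, led by SPARC at 422 ± 230 CPM, the laminin genes LAMB1 (204 ± 60.7 CPM for ENSDARG00000045524 and 95.6 ± 48.9 CPM for ENSDARG00000101209) and lama4 at 131 ± 33.8 CPM. Notch pathway genes had 14 of 22 above and 3 below, with LFNG at 370.3 ± 115 CPM, NOTCH3, the ligand gene DLD at 127 ± 46.0 CPM and MIB1 at 129.6 ± 125 CPM. Genes of PDGF and TGF-beta reception had 14 of 25 above and 3 below, with the BMP target genes ID1 at 1038 ± 502 and ID2 at 304 ± 129 CPM, SMAD1 at 101 ± 9.72 CPM and PDGFRB. None of the 3 lists differed from the pericyte list by the permutation test, at differences of 1.01, 0.62 and -0.22 log2 units (adjusted p = 0.477, 0.62 and 1.0), and for PDGF and TGF-beta reception the mean of the per-library differences had the other sign, at 0.24, as had the difference without B1, at 0.55. The mean of MIB1 was 67.4 CPM and that of NOTCH3 109 CPM without B1. Without B1 the IDs below the reference level were 4, 6 and 7. For the basement membrane list they were 1, 0 and 0 by edgeR without B2, B3 and B4, and 2, 2 and 1 at an unadjusted p under 0.05.

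Among 9678 genes of mean CPM of at least 10, 88 had a biological coefficient of variation of at least 1, and 58 of these were highest in B1, 11 in B2, 15 in B3 and 4 in B4. The 10 most variable genes with a symbol included the neuronal transcription factor genes TBR1 (155 CPM in B1, at most 7.73 in the others), EOMES (632 CPM in B1, at most 22.1), NEUROD6 (ENSDARG00000040008, 122 CPM in B1, at most 0.951) and TLX3 (41.1 CPM in B1, at most 0.335), and the proteoglycan gene gpc2 (87.8 CPM in B1, at most 1.90). Of the 10, bglapl, an osteocalcin gene, was at 290.2 CPM in B3 and 87.6 in B2 against at most 0.350 in the others, and spp1 at 258 and 75.9 CPM against at most 3.22. The cartilage matrix gene MATN1 was 98.0 CPM in B3 and 13.2 in B2, while the myoglobin gene mb (118 CPM) and crispld1b (49.7 CPM) were highest in B2. The number of variable genes fell to 18 without B1, 51 without B2 and 45 without B3. None of the 20 lists passed a test of enrichment among the variable genes (Fisher's exact test, lowest adjusted p = 0.62). The members found there were LUM, CLDN5 and OSR2. With 88 variable genes among 9678, lists of this size could hardly pass, so the test cannot tell whether a list varies. For the endothelium list, 1 variable member of 7 gave an unadjusted p of 0.062 by Fisher's exact test. Of the 12 neuron members in that test 0 were variable. Yet 25 of the 27 neuron IDs were higher in B1 than in the mean of B2 to B4.

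**Figure D3:**
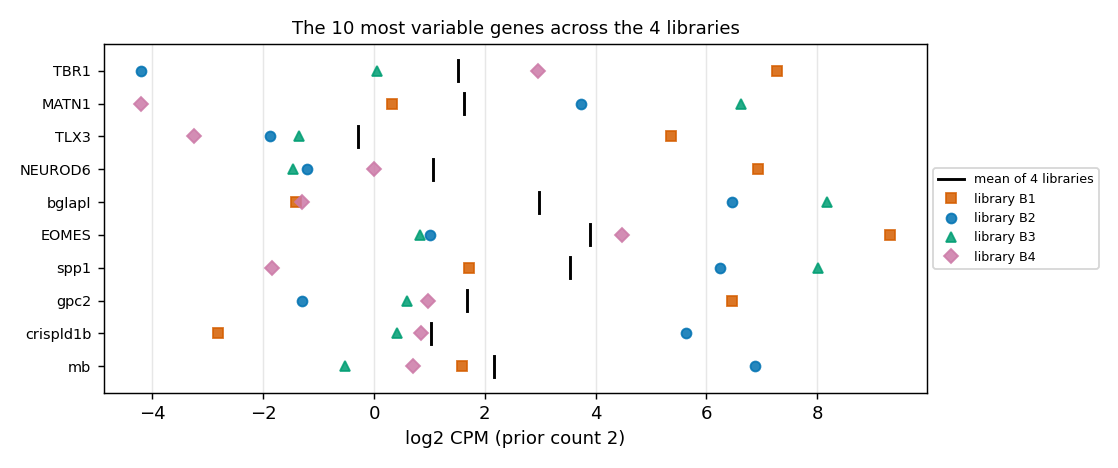
Level of the 10 most variable genes with a symbol, as log2 CPM with a prior count of 2, in the 4 libraries. Symbols are libraries and black bars their mean, and values far below 0 stand for a count of 0 or nearly 0; TBR1, TLX3, NEUROD6, EOMES and gpc2 are highest in B1, MATN1, bglapl and spp1 in B3, and crispld1b and mb in B2.

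Across genes, which are not independent replicates, log2 CPM of B1 correlated with that of B2, B3 and B4 at Pearson r = 0.789, 0.801 and 0.821, against 0.927 to 0.936 among those 3, in 6 pairs. The 11 IDs with the symbol of a mitochondrially encoded gene took 0.438% of counts in B1 against 2.29%, 1.55% and 1.46% in B2 to B4. Mitochondrially encoded IDs without a symbol are not in that share. The 10 most abundant IDs took 14.5% in B1 against 22.6% to 25.5% in the others. The chi-square per degree of freedom between pairs of libraries ran from 116 to 774, so no pair looked like a library deposited more than once. The deposited YuGene values ranked the genes of each library as the counts did (Spearman 1.0 across 32105 genes), and on that scale the list medians ran from 0.968 for immediate early and stress genes and 0.918 for radial glia through 0.630 for pericytes and 0.143 for endothelium to 0.0119 for neutrophils.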

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

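The tests of neuronal RNA and of amplification below were chosen only after the result was seen, and those of depth and of the most abundant genes before. A library was singled out where, on the log2 CPM scale, its gap to the nearest of the others exceeded Dixon's 95% critical share of the range of the 4, which chance does in about 1 of 20 cases. Among 111 genes examined 16 met this, where chance would give 5.55, and 11 of the 16 had B1 as the library apart. B1 was high in 5, with KCNE4 at 955 CPM (others at most 116), cnp at 469 (at most 80.9), MIB1 at 316 (at most 77.5), JUN at 30863 (at most 4586) and BTG2 at 23719 (at most 2245). It was low in 6, with the MFSD2A copy ENSDARG00000030630 at 32.2 CPM (others at least 70.9), GLUL at 6530 (at least 18839), ID1 at 286 (at least 1255), ID2 at 115 (at least 323), malat1 at 14650 (at least 48365) and si:ch211-276i12.12 at 3863 (at least 17038). Of 20 lists 1 met it, no more than chance would give, the housekeeping list with a median of 6.78 log2 CPM in B1 against 8.0 to 8.13.

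The pattern of B1 standing apart was weighed against technical explanations. Lower depth is argued against, since with all libraries thinned to 33270774 counts the lowest correlation among the other 3 still exceeded the highest with B1 by 0.104, where a gap under 0.05 was the prediction. Without the 100 most abundant genes the Spearman gap was 0.118, where a gap under 0.05 was the prediction, so the gap was not confined to those genes. A rank correlation over so many genes is little moved by 100 of them. This test could therefore hardly have pointed to them as the cause. More neuronal RNA in B1 may account for the neuron list, though B1 was also highest in the medians of the lymphatic and oligodendrocyte lists. If neuronal RNA only diluted radial glia RNA, the tested radial glia genes would have shifted together in B1. They did not, with an SD of shifts of 1.70 against at most 0.630 in the other libraries, a ratio of 2.70. This argues against dilution alone. Neuronal RNA that itself holds some of these transcripts was not tested, so it remains open as the whole cause. A sort for EGFP is meant to remove neurons without the reporter, but its purity is not known from these data. A bias of amplification or base composition cannot be told apart from a different mixture of cells, because no transcript sequence was used here. The 11 mitochondrially encoded genes with a symbol lay lower in B1 by a median log2 shift of -2.02. The design names no difference between the pools, so no biological explanation was tested.

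The other 3 libraries gave single values. In B2 the TAGLN copy ENSDARG00000045408 was 26.7 CPM against at most 9.29 in the others. In B4 ITGA8 was 154 CPM (at most 50.1 in the others), igf2b 130.5 (at most 80.5), si:ch211-251b21.1 14589 (at most 5263) and selenop 6425 (at most 3958).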

How the results depend on the processing

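The counts of list members without each library were added after the data had been seen, and all other alternatives were planned. The numbers of genes above the reference level stayed within 1.5 times of 6362 under 11 of 11 alternatives. Genes below it numbered 16928 with no filter, which adds genes of few counts, and genes detected numbered 10030 at a minimum of 5 CPM. Of 209 list comparisons under alternatives 193 kept their side of the threshold. These include changes of sign where neither value passed, as for PDGF and TGF-beta reception without B1 (0.55 against -0.22). Those that lost the call did so with tested genes only for smooth muscle (0.56), neutrophil (1.86) and angiogenic ligands (1.80); with list means for smooth muscle (1.92), endothelium (1.95), neuron (1.80), neutrophil (3.21) and angiogenic ligands (1.14); and on the YuGene scale for angiogenic ligands (0.335) and housekeeping (-0.284). The lymphatic list gained a call with tested genes only (2.26). Leaving out a library gave 1.79 to 2.11 for angiogenic ligands and -2.69 to -2.35 for housekeeping, whose call was lost without B4. Variable genes numbered 139 at a mean of at least 5 CPM, 25 at 50, 643 at a coefficient of variation of 0.7 and 5 at 1.5, and 18 to 71 without a library (18 without B1, 51 without B2, 45 without B3). Members below the reference level without a library ranged from 2 to 4 for smooth muscle, 1 to 4 for lymphatic, 1 to 9 for neuron, 0 to 3 for oligodendrocyte, 0 to 1 for neutrophil, 1 to 2 for epithelium, 0 to 4 for basement membrane, 3 to 9 for angiogenic ligands, 3 to 6 for notch and 2 to 7 for PDGF and TGF-beta reception, and members above from 1 to 2 for erythrocyte. Of the named genes' values under alternatives 823 kept their call, 25 lost it, 4 gained it and 6 changed sign with a call before or after the change. With limma-voom these were bglapl (-0.77) and spp1 (-0.22). Without a library they were EOMES (-0.55 to 4.05), gpc2 (-3.34 to 1.2), crispld1b (-3.67 to 0.48) and mb (-2.94 to 1.67), the lowest each without the library that carries the gene. At their negative values gpc2, crispld1b and mb passed as low, whereas bglapl, spp1 and EOMES passed on neither side. For the other alternatives the cause was not tested. Values per kilobase of exon were not run, because no annotation was used here. No paired analysis was possible because there is only 1 group. At 33270774 to 40441253 counts depth limits only genes near the floor of 0.0751 to 0.0879 CPM.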

Other observations

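The tests of abundant glial genes and of carry-over below were chosen only after the result was seen, as were the genes named in this part. The bone and cartilage lists were written after the variable genes were seen, and COL11A2 and epyc were taken out of the cartilage list after a first test that included them, since both are among the variable genes. Among the variable genes outside the 10 named in the report, the following single genes were highest in B1, with no test of a group, namely INSM1 at 169 CPM (at most 8.88 in the others), nhlh2 at 175 (at most 6.2), sox4a at 963 (at most 47.3) and SOX4 at 6315 (at most 317). The immediate early gene egr4 was 7993 CPM in B1 and at most 475 in the others, and the synapsin gene syn1 was 104 against at most 3.40. B2 held COCH at 12156 CPM against at most 1439 and the cartilage collagen gene COL2A1 at 886 against at most 84.9. B3 held the collagen gene COL10A1 (ENSDARG00000054753) at 393 CPM against at most 47.1 and bglap at 347 against at most 83.1.

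Bone and cartilage genes in B2 and B3 were examined with lists that left out the variable genes. These lists hold relatives of variable genes already seen to be high in these libraries, so a high percentile there was likely beforehand. Random lists of unrelated genes do not allow for genes that vary together, and some list members lay near the floor. The percentiles below therefore describe the shifts and are not an independent test of them. The median of 13 chondrocyte genes was shifted up by 2.01 log2 units in B2, above all of 10000 random lists matched on abundance (percentile 100), with cnmd at 226 CPM in B2 against at most 52.2 and MATN4 at 65.8 against at most 12.3. The median of 15 osteoblast genes was shifted up by 1.95 in B3 (percentile 100), with PHEX at 59.1 CPM against at most 15.8 and IFITM5 at 19.7 against at most 2.63. Of the chondrocyte IDs 9 of 13 were higher in B2 than in the mean of the other 3 libraries and 8 were highest there, with snorc highest in B3 (8.72 CPM). Of the osteoblast IDs 12 of 15 were higher in B3 than in the mean of the others, and 8 were highest there. The osteoblast list lay at percentile 97.1 in B2 and 19.6 in B1, and the chondrocyte list at 36.8 in B3 and 4.15 in B1. B4 was extreme the other way, with the osteoblast list at percentile 0 (0 of 15 IDs higher than in the mean of the others) and the chondrocyte list at 0.09 (4 of 13). More cartilage RNA in pool B2 and more bone RNA in pools B3 and B2 than in B4 may account for these shifts, as a hypothesis. EGFP-positive skeletal cells and carry-over of tissue at dissection were not separated. The sort for EGFP is meant to remove cells without the reporter, but its purity is not known from these data.

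Radial glia genes above pericyte genes were the other pattern weighed. Without its 5 most abundant IDs the radial glia list median still lay above the pericyte median in 4 of 4 libraries. The gap was 0.476 to 2.08 log2 units, so the pattern was not confined to those 5 IDs. A median is little moved by a few very abundant genes, so this test could hardly have pointed to them as the cause. Carry-over of brain cells of every type alike cannot be told apart from glial expression within the sorted gate, because no unsorted or EGFP-negative library was used here. The radial glia median exceeded the neuron median by 5.36 log2 units, and the ratio in whole brain is not known from these data. The sort for EGFP is meant to remove glia without the reporter, but its purity is not known from these data. No biological explanation was tested.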
